A study of Mus musculus with 6 samples.

How the data were processed

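RNA sequencing measured gene expression in mouse T helper 9 (Th9) cells, the IL-9-producing type of CD4 T helper cell, cultured with or without sphingosylphosphorylcholine (SPC, also called lysosphingomyelin), a bioactive lysophospholipid. Per the labels' protocols, naive CD4 T cells from the spleens of C57BL/6N mice were activated on plates with anti-CD3e (1 µg/ml) and anti-CD28 (1 µg/ml) in the presence of IL-4 (10 ng/ml), TGF-beta1 (2 ng/ml) and anti-IFN-gamma (10 µg/ml). SPC was given at 30 µM, and the cells were taken on day 3. Libraries were made from 1.3 µg of total RNA per sample with a kit that marks strand. The 6 libraries form 2 groups of 3, control and SPC, taken from the sample titles, which also number the libraries of each group from 1 to 3. The series text describes 3 independent experiments.

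The files hold raw read counts per gene symbol, 23183 symbols per library, as deposited by the authors. Per the submitters' processing notes, TopHat and the mm10 mouse genome build were used. The TopHat version, the counting program, the gene annotation and the strand setting of the counting are not given in the sources used here. No row stands for anything other than a gene. No symbol bore the prefix of mitochondrially encoded genes (mt-), so these could not be analysed. The constant segments of T cell receptor and immunoglobulin genes were not analysed here. Total counts per library lay between 22002050 and 33049997, and between 14718 and 15114 genes had a count. Where strand was not used in counting, reads of overlapping genes on opposite strands cannot be told apart, and reads of close paralogs can be split between them.

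Gene symbols were matched to GENCODE M21 (GRCm38, the assembly that mm10 names) for coordinates, GC content and transcript length. In all, 98.41% of the symbols matched, 22148 directly and 666 through a RefSeq synonym. Coordinates are 1-based and cover the annotated gene, introns included.

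The deposited counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, robust dispersion estimates, scaling by the trimmed mean of M values (TMM) and group as the single term. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which kept 12226 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Normalised counts are TMM-scaled CPM unless stated otherwise, given as mean ± SD over the 3 libraries of a group. Log2 fold changes are SPC over control, given ± SE, where the SE is the log2 fold change divided by the square root of F. Each adjusted p of a gene is from this test unless another is named. Groups of 3 against 3 cannot give an exact permutation p below 0.10, so no test on single genes by permutation was made.

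Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, over the 44 lists with at least 5 tested members of the 50 fixed lists, with Benjamini-Hochberg adjustment over those lists. Camera compares a list with the other genes. The lists cover Th9 cytokines and effectors, Th9 transcription factors, factors that restrain Th9 cells, the other T helper, regulatory and follicular programs, activation, quiescence and exhaustion genes, cytokine signalling, receptors and metabolism of lysophospholipids and sphingolipids, other lipid, stress, energy, growth, cell cycle and cell death programs, markers of other cell types, T cell lineage genes and 3 sets that reflect library quality. Of the 3 library quality sets, that of mitochondrially encoded genes had no member and gives no reading. Beside the number of members called among all tested genes, the number called when adjusted over the list alone is given.

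Genes are named by a rule. It takes Il9 and a set of Th9 and lineage genes, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes with a mean of at least 5 CPM and no overlap between the groups, predicted genes left out, and up to 4 members with the smallest p in each list that was called or held at least 3 called genes. A few genes that it takes are not reported here. Sla and the markers of other cell types named in the report fall outside it and were chosen after the data were seen, as were the further genes listed in the observations. The groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

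Libraries were compared first. The chi-square statistic per degree of freedom of each pair of libraries lay between 4.82 and 34.8 within groups, so no pair agreed within counting noise. The pairing of the numbered libraries was checked from the deviation of each library from its group mean. The deviations of same-numbered libraries correlated at 0.413, 0.208 and 0.508 across genes, all above the limit of 0.1 set for pairing, and each library correlated best with its own number. Across genes these are not independent replicates. The numbers were therefore taken to pair the libraries, though no label states that a number marks the same experiment in both groups. The group-only test had been fixed before the data were examined and stayed the main one. The values from the fit with the replicate number as a block are printed where they change a call. The common biological coefficient of variation was 11.2% without and 6.34% with the block.

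The scripts were tested on simulated data with 3 against 3 libraries of the real depths. With independent libraries and 12144 tested genes, the group-only test recovered 72.3% of genes changed 1.5-fold, 89.6% at 2-fold and 100% at 4-fold, and 5.46% of its calls were false. With number effects added and 12135 tested genes, the group-only test recovered 58.2%, 83.6% and 96.9% at these folds, and the blocked test 85.1%, 92.5% and 100%. On independent libraries the blocked test recovered 67.7%, 88.1% and 100%, with 3.43% of its calls false. With number effects, 0% of group-only and 2.13% of blocked calls were false. Each simulated gene had the dispersion of the abundance trend, and number effects were drawn for each gene separately. The real spread can differ from both, so the rates check the scripts and do not give the power on these data.

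Alternatives were other scalings (relative log expression, upper quartile, total count), other filters (none, or 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate block in edgeR and DESeq2, stricter thresholds, leaving out each library or number, an estimated inter-gene correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes. A correction of each library for GC content and transcript length (a loess of span 0.5, 99.3% of tested genes with both values), the newer quasi-likelihood method of edgeR, leave-outs of the blocked count, and the estimated correlation and fry with the block were added after seeing the data.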

Results

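Expression was measured by RNA sequencing in mouse Th9 cells on day 3 of culture, in 3 control libraries and 3 libraries of cells given 30 µM SPC. The control libraries held 29528938, 30292992 and 22002050 counts and the SPC libraries 33049997, 26015703 and 22715292. The 10 most counted genes took 4.92% to 5.52% of the counts and genes of cytosolic ribosomal proteins 7.27% to 8.09%. The first principal component (39.7% of the variance) did not part the groups, with control libraries at -8.15, 4.25 and 29.7 and SPC libraries at -26.5, -8.95 and 9.68. Its values rose with the library number in both groups. The second component (28.3%) parted the groups, with control libraries between 3.19 and 18.9 and SPC libraries between -23.6 and -4.89.

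The comparison asks how SPC changes gene expression in cells differentiating under Th9 conditions. Il9, the cytokine gene that defines the Th9 state, rose 2.11-fold, from 539 ± 18.8 CPM in control to 1138 ± 239 CPM with SPC (SD, n = 3 each). The interferon-inducible GTPase genes Gbp2 and Gbp5 rose 4.73-fold and 4.33-fold. Itgb3, an integrin beta chain gene, fell from 67.3 ± 2.43 to 24.1 ± 1.77 CPM, and Gzmb, which encodes the cytotoxic protease granzyme B, fell from 10.2 ± 3.90 to 1.96 ± 0.45 CPM. Gpr65, which encodes a proton-sensing receptor, fell from 19.4 ± 4.46 to 6.42 ± 1.04 CPM.

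Of 12226 tested genes, 59 differed between the groups (edgeR, adjusted p under 0.05), 40 higher and 19 lower with SPC. At an unadjusted p under 0.05 there were 1250. With the replicate number as a block, 866 genes differed, 491 higher and 375 lower, and the 59 were all among them in the same direction. Of the 59 genes, 16 rose and 8 fell by at least 2-fold, and in the blocked test 73 rose and 38 fell by that much. The largest fold was 5.73 among higher and 5.23 among lower genes. The gene with the 5.73-fold rise had 0.233 CPM in control and 1.36 CPM with SPC, too low to be named by the rule. The median log2 fold change of all tested genes was 0.00193. The count was 6 without control library 2 and 6 without SPC library 2, 28 without control library 3, 35 without SPC library 3 and 38 without control library 1. It was 0 in the edgeR test without both libraries numbered 2, where 502 genes had an unadjusted p under 0.05, and the blocked count lay between 563 and 2112 when a number was left out.

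**Figure D1:**
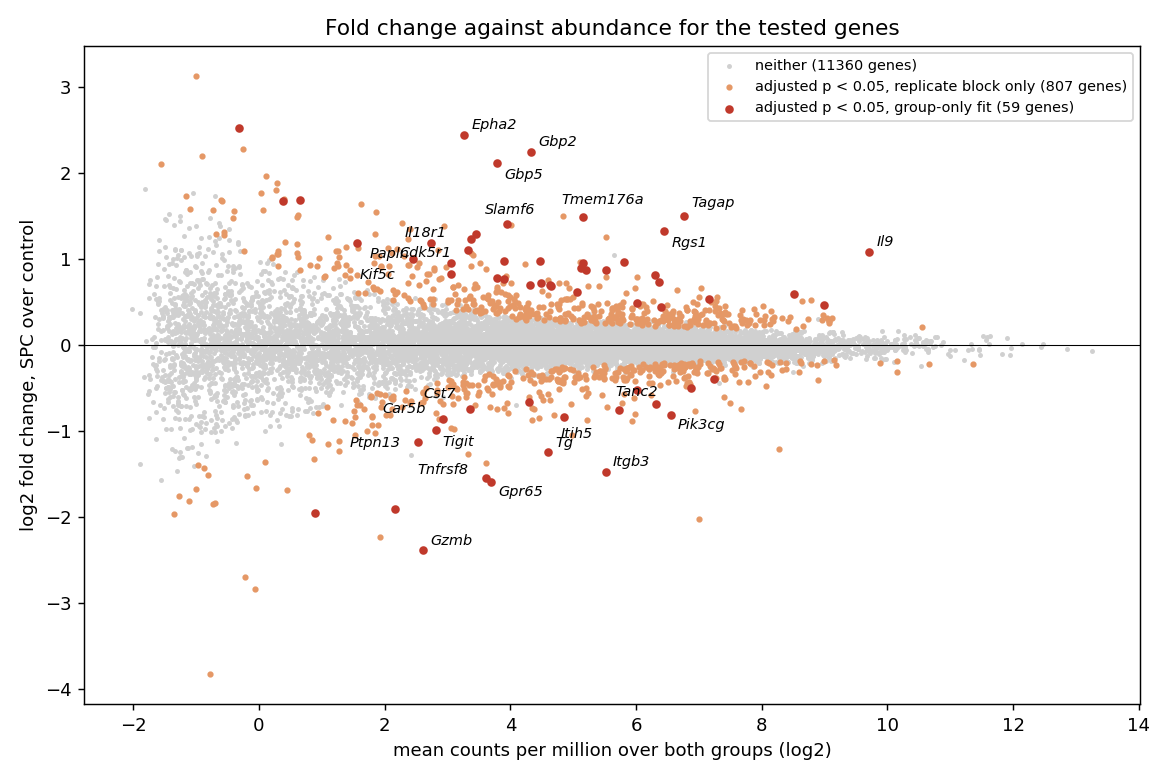
Log2 fold change (SPC over control) of the 12226 tested genes against their mean CPM over both groups on a log2 scale. Red points are the 59 genes called in the group-only test, orange points are genes called in the blocked test alone and grey points are neither. Labels mark the 12 higher and 12 lower called genes that the rule takes by largest log2 fold change. Il9 lies at the highest abundance among the labelled genes.

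Il9 lies on chromosome 13 (56479277 to 56482246, minus strand, mm10). Its log2 fold change was 1.08 ± 0.13 (adjusted p = 0.0189, and 0.00115 with the block), and it was higher in all 3 same-numbered pairs. The control libraries gave 559, 536 and 522 CPM and the SPC libraries 981, 1020 and 1412 CPM. The fold change stayed between 0.87 and 1.20 on the log2 scale when a library or a number was left out, but its call was lost without control library 2 (adjusted p = 0.112), without SPC library 2 (0.0757), without both libraries numbered 1 (0.0637) and without both numbered 2 (0.328).

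Of the other 11 named genes that were higher with SPC, Epha2, an ephrin receptor tyrosine kinase gene, rose from 3.00 ± 0.70 to 16.2 ± 8.35 CPM (log2 fold change 2.44 ± 0.37, adjusted p = 0.0373). Gbp2 (chromosome 3, 142620602 to 142638008) rose from 7.04 ± 0.21 to 33.3 ± 7.25 CPM (2.24 ± 0.16, adjusted p = 0.00192). Gbp5 (chromosome 3, 142493978 to 142522344) rose from 5.22 ± 1.51 to 22.5 ± 6.99 CPM (2.11 ± 0.27, adjusted p = 0.0200). Of the 50-base windows of the longest transcripts of Gbp2 and Gbp5, 2.07% and 2.46% also occur in a transcript of another gene. Tagap, a GTPase-activating protein gene of activated T cells, rose from 56.7 ± 2.56 to 159.9 ± 28.3 CPM (1.49 ± 0.12, adjusted p = 0.00264), and Rgs1, a regulator of G protein signalling, from 49.8 ± 0.50 to 124.7 ± 16.8 CPM (1.32 ± 0.10, adjusted p = 0.00210). Slamf6, a receptor of the SLAM family, and Il18r1, a chain of the IL-18 receptor, rose by 1.40 ± 0.15 and 1.29 ± 0.19 on the log2 scale (adjusted p = 0.0138 and 0.0367). Tmem176a rose by 1.49 ± 0.21 (adjusted p = 0.0339). Papln, Cdk5r1, which encodes an activator of Cdk5, and Kif5c, a kinesin heavy chain gene, rose by 1.18 ± 0.20, 1.11 ± 0.14 and 0.99 ± 0.16 (adjusted p = 0.050, 0.0210 and 0.0470).

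Among the 12 named genes that were lower with SPC, Itgb3 (chromosome 11, 104608000 to 104670476) had the smallest p of all tested genes, with a log2 fold change of -1.48 ± 0.08 (adjusted p = 0.00042). Gzmb (chromosome 14, 56258838 to 56262260) had the largest fold, -2.39 ± 0.31 on the log2 scale (adjusted p = 0.0213). Gpr65 (chromosome 12, 98268635 to 98276644) had a log2 fold change of -1.59 ± 0.19 (adjusted p = 0.0164), and Tnfrsf8, which encodes the receptor CD30, of -1.55 ± 0.23 (adjusted p = 0.0372). Tg, the thyroglobulin gene (chromosome 15, 66670753 to 66850721), fell from 34.2 ± 7.05 to 14.4 ± 0.38 CPM (-1.25 ± 0.14, adjusted p = 0.0164). Sla lies inside Tg on the opposite strand. In all, 1.26% of the exonic bases of Tg lie in an exon of another gene, and none of these in an exon of Sla. Tigit, a co-inhibitory receptor gene, Ptpn13, a tyrosine phosphatase gene, and Pik3cg, which encodes the catalytic gamma subunit of phosphoinositide 3-kinase, had log2 fold changes of -0.99 ± 0.17, -1.13 ± 0.19 and -0.82 ± 0.12 (adjusted p = 0.0489, 0.0489 and 0.0358). Car5b, a mitochondrial carbonic anhydrase gene, Itih5, Tanc2 and Cst7, which encodes cystatin F, had log2 fold changes between -0.86 and -0.75 (adjusted p between 0.0164 and 0.0474).

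**Figure D2:**
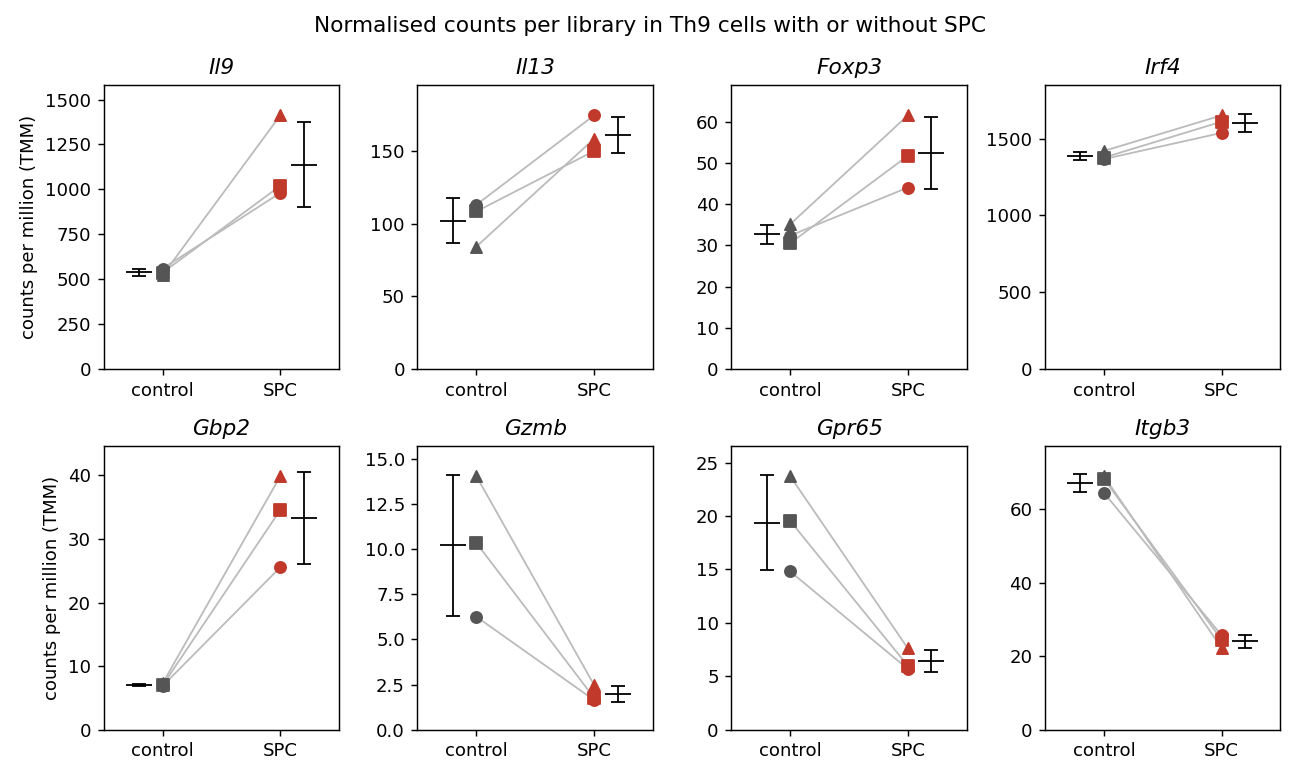
TMM-scaled CPM of 8 genes in each library, control in grey and SPC in red, with grey lines joining libraries of the same number (circle 1, square 2, triangle 3) and black marks giving mean ± SD (n = 3). The 3 SPC libraries lie above the 3 control libraries for Il9, Il13, Foxp3, Irf4 and Gbp2 and below them for Gzmb, Gpr65 and Itgb3, while Il13, Foxp3 and Irf4 did not pass the group-only test.

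Of the 13 tested Th9 cytokine and effector genes, Il9 rose and Gzmb fell, and adjusted over the list alone 4 rose and 5 fell. With the block 4 rose and 5 fell among all tested genes. The list as a whole was not called (median log2 fold change -0.25, mean 0.02, camera adjusted p = 0.545). Il10, an anti-inflammatory cytokine gene, had 3.42 ± 0.48 CPM in control and 1.43 ± 0.23 CPM with SPC (log2 fold change -1.24 ± 0.21, adjusted p = 0.0514, and 0.00389 with the block). Il21 stood at 1.10 ± 0.14 and 0.70 ± 0.06 CPM (-0.65 ± 0.26, adjusted p = 0.419). Of the 24 tested Th9 transcription factor and signalling genes none was called in the group-only test (6 genes lower and 4 higher with the block, 4 each way when adjusted over the list alone without it), and the list was not called (median 0.03, mean -0.03, camera adjusted p = 0.808). Irf4, a transcription factor needed for Il9 expression, had 1387 ± 28.3 and 1599 ± 57.5 CPM (0.21 ± 0.06, adjusted p = 0.247, and 0.0184 with the block). Batf, its partner, had a log2 fold change of 0.11 ± 0.09 (adjusted p = 0.790) and Gata3, the main Th2 factor, of -0.17 ± 0.08 (adjusted p = 0.542). Spi1, which encodes the factor PU.1, had 1, 2 and 0 counts in the control and 1, 0 and 1 in the SPC libraries, and was too low to be tested. The 13 factors reported to restrain Th9 cells had a median of 0.00 with none called (2 higher when adjusted over the list alone, 3 higher and 1 lower with the block, camera adjusted p = 0.715).

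The Th2 list was lower with SPC (15 tested genes, median log2 fold change -0.34, camera adjusted p = 0.00040, and adjusted p = 0.253 with an estimated correlation). Ccr8, a chemokine receptor gene, was its called member and fell from 137 ± 4.93 to 97.1 ± 7.03 CPM (-0.50 ± 0.08, adjusted p = 0.0373). Adjusted over the list alone, 7 members fell and 1, Il13, rose, and with the block 6 fell and 1 rose among all tested genes. Crem and Ppp2r3a had log2 fold changes of -1.05 ± 0.19 and -0.38 ± 0.07 (adjusted p = 0.0538 and 0.0627, with the block 4.0e-05 and 0.00622). Il13 had 101.8 ± 15.5 CPM in control and 160.9 ± 12.4 CPM with SPC (0.66 ± 0.12, adjusted p = 0.0530, with the block 0.00056). Il4 had a log2 fold change of -0.34 ± 0.11 (adjusted p = 0.331) and Il5 of 0.03 ± 0.15 (adjusted p = 0.978), and neither was called with the block.

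The Th17 list was higher (13 tested genes, median 0.48, camera adjusted p = 0.00035, and adjusted p = 0.290 with an estimated correlation). Its called members were Rora, a nuclear receptor gene, which rose from 32.5 ± 1.36 to 59.3 ± 8.55 CPM (0.87 ± 0.11, adjusted p = 0.0200), and Tmem176a. Adjusted over the list alone 6 rose, and with the block 7 rose among all tested genes. Tmem176b had a log2 fold change of 1.25 ± 0.22 (adjusted p = 0.0514, with the block 2.5e-05). The annotated ends of Tmem176a (chromosome 6, 48840919 to 48847071) and Tmem176b (48833818 to 48841496) overlap on opposite strands. Ccr6, a chemokine receptor gene, had 0.58 ± 0.15 (adjusted p = 0.171, with the block 0.00175). Il17a had 14, 0 and 2 counts in the control and 15, 2 and 5 in the SPC libraries and was too low to be tested.

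In the other T helper programs, the Th1 and cytotoxic list (17 tested genes, median -0.15, camera adjusted p = 0.153) held 1 called gene in each direction, Il18r1 higher and Gzmb lower, with 3 higher and 4 lower when adjusted over the list alone and as many with the block. Tbx21, which encodes the main Th1 factor, had 4.78 ± 1.33 and 4.78 ± 1.58 CPM (log2 fold change 0.00 ± 0.28, adjusted p = 0.999), and Ifng, at 0.89 ± 0.45 and 0.43 ± 0.34 CPM, had -1.01 ± 0.59 (adjusted p = 0.646). The regulatory T cell list (20 tested genes, median 0.14, camera adjusted p = 0.098) held no called gene, 5 higher and 2 lower ones when adjusted over the list alone, and 7 higher and 4 lower ones with the block. Foxp3, the regulatory T cell factor, had 32.7 ± 2.32 and 52.5 ± 8.79 CPM (0.68 ± 0.12, adjusted p = 0.0577, with the block 0.00087). The follicular helper list was not called (14 tested genes, median 0.09, camera adjusted p = 0.505), with Slamf6 as its called gene and 3 higher and 1 lower when adjusted over the list alone and as many with the block.

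NF-kappaB response genes were higher (22 tested genes, 19 of them above 0, median 0.30, camera adjusted p = 6.3e-08, and adjusted p = 0.253 with an estimated correlation). Called members were Nfkb2, a subunit of the noncanonical pathway (0.46 ± 0.07, adjusted p = 0.0358), Traf1, a signalling adaptor (0.73 ± 0.11, adjusted p = 0.0360), and Ltb, which encodes lymphotoxin beta (0.54 ± 0.09, adjusted p = 0.0441). Adjusted over the list alone 9 rose, and with the block 11 rose among all tested genes. Icam1, an adhesion molecule gene, had 0.40 ± 0.07 (adjusted p = 0.0530, with the block 0.00422).

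Genes of cholesterol synthesis and uptake were higher by small folds (28 tested genes, 24 of them above 0, median 0.17, camera adjusted p = 7.5e-07, and adjusted p = 0.253 with an estimated correlation). None was called among all tested genes, 9 rose when adjusted over the list alone, and 10 rose with the block. Msmo1 and Mvd, enzymes of sterol synthesis, had log2 fold changes of 0.36 ± 0.07 and 0.30 ± 0.06 (adjusted p = 0.0727 and 0.0881, with the block 0.00273 and 0.00662). Pmvk, another enzyme of the pathway, had 0.33 ± 0.09 (adjusted p = 0.207, with the block 0.0265).

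The p53 target list was higher (24 tested genes, median 0.27, camera adjusted p = 5.0e-05, and adjusted p = 0.253 with an estimated correlation), with Epha2 as its called member, 5 higher and 1 lower when adjusted over the list alone, and 10 higher and 1 lower with the block. Pmaip1 and Fas, which promote apoptosis, had log2 fold changes of 0.57 ± 0.11 and 0.64 ± 0.13 (adjusted p = 0.0636 and 0.0779, with the block 0.00278 and 0.00296), and Tnfrsf10b 0.33 ± 0.08 (adjusted p = 0.162, with the block 0.0282). The TGF-beta response list was higher (20 tested genes, median 0.21, mean 0.08, camera adjusted p = 0.00185, and adjusted p = 0.253 with an estimated correlation), and its adjusted p was 0.0566 without both libraries numbered 2. Id1, an inhibitor of DNA-binding factors, was its called member (0.61 ± 0.09, adjusted p = 0.0339), 5 rose when adjusted over the list alone, and 6 rose and 2 fell with the block. Ldlrad4, Tgfbr1 and Id3 had log2 fold changes of 0.67 ± 0.15, 0.30 ± 0.08 and 0.50 ± 0.14 (adjusted p = 0.102, 0.191 and 0.208, with the block 0.00829, 0.00656 and 0.0406).

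Lists of proliferation genes were slightly lower. Mitosis genes (35 tested genes, median -0.09, camera adjusted p = 0.00355, and adjusted p = 0.253 with an estimated correlation) and DNA replication genes (34 tested genes, median -0.08, camera adjusted p = 0.0146, and adjusted p = 0.914 with an estimated correlation) held no called member, also when adjusted over each list alone, and 2 lower ones each with the block. Ttk and Plk1, mitotic kinase genes, had log2 fold changes of -0.41 ± 0.11 and -0.20 ± 0.08 (adjusted p = 0.173 and 0.434, with the block 0.0125 and 0.0421). Mki67 and Kif23 had -0.25 ± 0.11 and -0.18 ± 0.06 (adjusted p = 0.492 and 0.338). Mcm2 and Ccne1 had -0.20 ± 0.07 and -0.22 ± 0.13 (adjusted p = 0.313 and 0.633, with the block 0.0329 and 0.0471), and Cdt1 and Chaf1b had -0.21 ± 0.07 and -0.20 ± 0.08 (adjusted p = 0.357 and 0.386). The mitosis call was lost without SPC library 3 (adjusted p = 0.063), and the DNA replication call without SPC library 3 (0.667), control library 1 (0.362), control library 2 (0.113) and both libraries numbered 2 (0.104). Replication histone genes (43 tested genes, median -0.25, camera adjusted p = 0.00042, and adjusted p = 0.880 with an estimated correlation), none of them called, took 0.0125% of the counts in control library 3 and 0.00689% to 0.00778% in the other libraries. Without control library 3 their adjusted p was 0.75, and 0.864 without both libraries numbered 3. Hist1h2bc, Hist1h2bj, Hist1h4k and Hist1h3c had log2 fold changes between -1.01 and -0.35 (adjusted p between 0.350 and 0.561).

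Among the 15 tested lysophospholipid and proton-sensing receptor genes, Gpr65 was called and the list was not (median -0.05, camera adjusted p = 0.565, with 1 higher and 1 lower when adjusted over the list alone and as many with the block). S1pr1, a sphingosine-1-phosphate receptor gene, had 20.5 ± 2.48 and 19.0 ± 2.06 CPM (-0.11 ± 0.12, adjusted p = 0.849), and Gpr132 had 56.9 ± 12.4 and 54.8 ± 6.35 CPM (-0.05 ± 0.15, adjusted p = 0.948). None of the 39 tested sphingolipid metabolism genes was called, also when adjusted over the list alone (median -0.03, camera adjusted p = 0.727), and 2 were higher and 3 lower with the block.

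**Figure D3:**
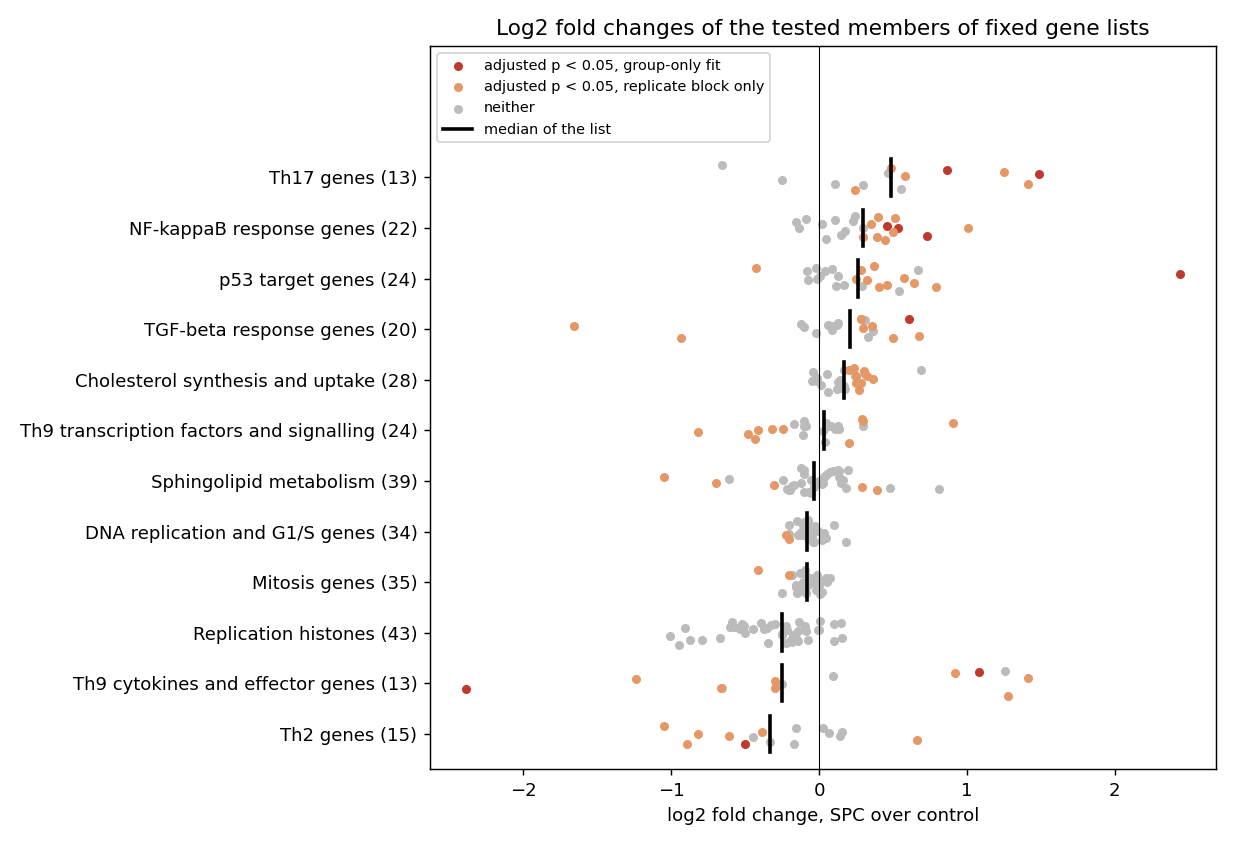
Log2 fold change (SPC over control) of each tested member of the 9 called gene lists and of 3 other lists central to the comparison, with the number of tested members in brackets and the list median as a black bar. Red points passed the group-only test, orange points the blocked test alone and grey points neither. The medians run from -0.34 for the Th2 list to 0.48 for the Th17 list.

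In the blocked test alone, 3 further lists were called. These were glycolysis genes, which were lower (median -0.11, adjusted p = 0.0733, with the block 0.00354), T cell cytokines and chemokines, which were higher (median 0.22, adjusted p = 0.0735, with the block 0.00617), and dendritic cell markers, which were higher (median 0.39, adjusted p = 0.098, with the block 0.00617). With the block and an estimated correlation the adjusted p was 0.766, 0.509 and 0.761 for these lists. Adjusted over each list alone, none of 22 glycolysis genes, 8 higher and 3 lower of 32 cytokine genes and none of 7 dendritic cell genes were called without the block. With the block, among all tested genes, 2 glycolysis genes were lower, 12 cytokine genes higher and 2 lower, and 4 dendritic cell genes higher. These 4 were Ccl17, Ccl22, Zbtb46 and Ccr7, of which Ccl17 and Ccl22 also stand in the Th9 effector list and Ccr7 in the naive T cell list. Ccl17 stood at 2.64 CPM in control and 5.05 CPM with SPC and Ccl22 at 2.09 and 5.14 CPM, while Itgax, which marks dendritic cells, stood at 0.0113 and 0.0522 CPM. The genes named in this paragraph and the next fall outside the naming rule and were chosen after their values were seen. CPM values in these paragraphs are scaled by the total count of each library, without TMM.

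Of the B cell markers, Cd74 stood at 60.2 and 82.1 CPM in control and SPC and H2-Ab1 at 18.2 and 13.2 CPM (5 tested genes, median 0.30, camera adjusted p = 0.377). Neither was called in the group-only test (adjusted p = 0.117 and 0.767), and with the block Cd74 was higher and H2-Ab1 lower (adjusted p = 0.00155 and 0.00662). The lists of monocyte, macrophage and neutrophil (3 tested genes), NK, CD8 and gamma-delta T cell (2), mast cell and basophil (1), erythroid and platelet (2) and fibroblast and endothelial markers (4) had too few tested members for the list test, and no member was called in the group-only test over all genes. Adjusted over each list alone, 1 gene was higher and 1 lower in the monocyte list and 1 was higher in the mast cell list, and 1 B cell gene was higher. With the block, Ctss was higher (adjusted p = 0.0636 without and 0.00551 with it) and Adgre1 lower (0.130 and 0.0315) among the monocyte markers, and Pecam1 was lower among the endothelial ones (0.456 and 0.0354). The other 3 lists held no call with the block. By their mean over both groups, the most abundant genes of the 5 lists were Ctss at 27.5 and 37.2 CPM, Cd8b1 at 1.74 and 2.02 CPM, Hdc at 0.665 and 1.09 CPM, Itga2b at 0.892 and 0.958 CPM and Pecam1 at 8.41 and 5.87 CPM. T cell lineage genes (15 tested genes, median -0.07, camera adjusted p = 0.757) and cytosolic ribosomal protein genes (82 tested genes, median -0.0042, camera adjusted p = 0.688) were not called as lists. Of the T cell lineage genes 1 was higher and 1 lower when adjusted over the list alone and 2 each way with the block, and 1 ribosomal protein gene was lower with the block.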

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

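The newer quasi-likelihood method, the GC and length correction, the leave-outs of the blocked count, and the estimated correlation and fry with the block were chosen after seeing the data. Each of the 59 called genes kept its sign in every alternative fit. The groups overlapped in none of the 59, so the leave-outs could hardly have changed a sign. The count was 59, 55 and 54 with relative log expression, upper-quartile and total-count scaling, 56 with the 1 CPM filter and 69 with the newer quasi-likelihood method, and 59, 53, 52, 55 and 58 of the 59 genes remained. It was 147 (97 higher, 50 lower, 57 of the 59 kept) with no filter, 279 (179 and 100, all 59 kept) with DESeq2 and 44 (32 and 12, all among the 59) with limma-voom. An adjusted p under 0.01 left 5 genes (4 and 1), a 2-fold minimum 24 (16 and 8) and a test against a fold of 1.5 left 4 (3 and 1). The GC and length correction gave 127 (81 and 46, 57 kept). With the replicate block there were 866 genes (491 and 375), 638 (351 and 287) with DESeq2 and the block, and 1221 (694 and 527) with the correction and the block, and each of these held all 59. The causes of these shifts between tests were not tested. Among the genes and lists reported here, the block changed no call other than those given beside the results.

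Leaving out a library or a number gave 0 to 66 genes, 0 to 53 higher and 0 to 16 lower ones. Of the 59 genes, 28, 5 and 25 remained without control library 1, 2 and 3, 38, 6 and 30 without SPC library 1, 2 and 3, and 15, 0 and 23 without both libraries numbered 1, 2 and 3. Fewer samples leave fewer degrees of freedom. In the group-only test the libraries numbered 2 weighed most. Without them, libraries 1 and 3 of each group remained, the least alike pair within it. Their chi-square per degree of freedom was 21.5 in control and 34.8 with SPC. Whether this caused the loss of calls was not tested. With the block, leaving out number 1, 2 and 3 gave 2112, 699 and 563 genes. The log2 fold change of Il9 ranged from 0.87 to 1.20 in the leave-outs. Il9 passed with the other scalings and filters, DESeq2, limma-voom and the newer quasi-likelihood method. It also passed with the block and the GC and length correction (adjusted p at most 0.0480 in all these fits). With an adjusted p of 0.0189 in the main edgeR test, Il9 missed the stricter limit on the adjusted p. Its result in the test against a fold of 1.5 was not computed. Lists called higher numbered 4 to 8 and lists called lower 3 to 7, against 5 and 4 in the main test. With an estimated correlation, with or without the block, 0 lists were called higher and 0 lower, and fry called 0 and 0 (lowest adjusted p 0.0527). With the block fry called 4 lists higher and 0 lower, which were the Th17, cholesterol, NF-kappaB and interferon-stimulated lists. The last had a negative median (-0.13).

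Uncalled values near 0 changed sign. Tbx21 stood at -0.0059 with limma-voom, -0.0038 with the block, -0.0142 with DESeq2 and the block, -0.0395 with the GC and length correction, and -0.0448 with the correction and the block. In the leave-outs Tbx21 ranged from -0.24 to 0.24, Il5 from -0.10 to 0.19, S1pr1 from -0.21 to 0.067 and Gpr132 from -0.14 to 0.14. The cause was not tested. The depth limits what can be said of Spi1, Il17a and other genes with a few counts per library, whose differences were not detectable here.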

Other observations

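The test of a general interferon response and the GC and length correction were chosen after the results were seen. The genes named in the next paragraph, Fads2, Sla, Ifit1, Ifih1, Oasl1, Isg15, Igtp, Ddx58 and Oas3 were also chosen then and fall outside the naming rule.

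Further genes were called outside the naming rule. Cd69, an early activation marker, rose from 24.3 ± 0.91 to 45.2 ± 1.97 CPM (log2 fold change 0.90 ± 0.08, edgeR adjusted p = 0.00310). Bcl2l1, which encodes the survival protein Bcl-xL, rose by 0.59 ± 0.09 (adjusted p = 0.0434), Tnfsf8, which encodes the CD30 ligand, by 0.96 ± 0.14 (0.0339), Pdgfb by 0.81 ± 0.11 (0.0258) and Adora2a, an adenosine receptor gene, by 0.97 ± 0.12 (0.0200). Csf2rb, a receptor chain shared by IL-3, IL-5 and GM-CSF, had a log2 fold change of -1.91 ± 0.22 (0.0164) and Cblb, a ubiquitin ligase that restrains T cell activation, of -0.69 ± 0.11 (0.0412). Of the co-inhibitory list, Ctla4 stood at 431.7 ± 166 CPM in control and 185.7 ± 70.2 CPM with SPC and Lag3 at 26.2 ± 6.04 and 15.5 ± 3.28 CPM. Cd200 and Nt5e of the same list had log2 fold changes of 0.34 and 0.45. All 4 missed the group-only threshold (adjusted p = 0.168, 0.158, 0.0768 and 0.163) and passed it with the block (5.0e-07, 0.00029, 0.00353 and 0.0106).

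The remaining 21 fixed lists were not called by camera. Some held called genes: T cell receptor response genes (median log2 fold change 0.01, adjusted p = 0.970, Cd69 higher), co-inhibitory receptors (0.07, 0.790, Tigit lower), IL-2 and STAT5 response genes (-0.04, 0.688, Bcl2l1 higher), chemokine receptors and integrins (0.05, 0.970, Ccr8 lower), apoptosis regulators (0.06, 0.0735, Bcl2l1 higher), hypoxia response (-0.05, 0.897, Rora higher), fatty acid synthesis (0.04, 0.970, Fads2 higher) and interferon-stimulated genes (-0.13, 0.494, Gbp2 and Gbp5 higher). Adjusted over each list alone these held 3, 3, 3, 2, 5, 1, 1 and 5 higher and 2, 3, 5, 2, 1, 0, 0 and 3 lower genes, and with the block 5, 2, 4, 5, 8, 3, 2 and 6 higher and 6, 3, 7, 3, 2, 6, 3 and 3 lower genes. In the group-only test over all genes, none was called in the lists of naive and quiescence genes (0.03, 0.851), Wnt genes (-0.01, 0.970), LXR targets (0.05, 0.970), lysosome genes (0.04, 0.188), the integrated stress response (0.05, 0.402), the unfolded protein response (0.03, 0.688), oxidative stress (0.01, 0.580), heat shock (-0.04, 0.314), mitochondrial respiration (0.01, 0.808), one-carbon and nucleotide synthesis (-0.04, 0.239), ribosome biogenesis (0.01, 0.897), lipid droplet and fatty acid oxidation (0.00, 0.851) and cytoskeleton genes (-0.02, 0.975). Adjusted over the list alone, these held calls for naive genes (3 higher, 2 lower), lysosome genes (1 higher), oxidative stress (1 lower) and cytoskeleton genes (2 each way). With the block there were 6 higher and 3 lower naive genes, 5 and 1 of the integrated stress response, 4 and 0 lysosome genes, 3 and 1 of oxidative stress, 2 and 2 cytoskeleton genes, 1 and 1 Wnt genes, and 1 higher gene each of the LXR targets, the unfolded protein response and the lipid droplet list, and none in the other 4 lists. Among the 35 lists that were not called, median, mean and test differed in sign in 13, and in none of the 9 called lists.

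Tg, the thyroglobulin gene, is best known from the thyroid, and its fall to 14.4 CPM could come from other transcripts counted in its interval. Sla, which lies inside Tg on the opposite strand, had a log2 fold change of -0.22 ± 0.07 (adjusted p = 0.247, with the block 0.0318) against -1.25 ± 0.14 for Tg, a difference of 6.51 standard errors, which argues against reads of Sla as the source. Exons of other annotated genes, Sla not among them, cover 1.261% of the exonic bases of Tg, which argues against shared exons. A change in Tg transcription with SPC and unannotated transcripts in the interval stay open. The call was lost without control library 2 (adjusted p = 0.0887), without SPC library 2 (0.126) and without both (0.426).

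Gbp2 and Gbp5 rose together, while the interferon-stimulated list was not called by camera. Fry with the block called the list higher (adjusted p = 0.0332), though its median was negative (-0.13). Reads shared between paralogs are argued against by the windows of their transcripts, of which at most 2.455% occur in another gene. A general interferon response might raise both genes, but the upper 95% bound of the log2 fold change reached 1 in 18.5% of the 27 other interferon-stimulated genes tested, whose median was -0.17 with 7 above 0. With the block, 4 of these rose and 3 fell. Ifih1 rose from 11.4 CPM in control to 15.5 CPM with SPC. Ifit1 (0.545 and 1.87 CPM), Oasl1 (0.294 and 1.39) and Isg15 (1.5 and 3.15) rose at low counts. Igtp (58.5 and 48.6 CPM), Ddx58 (9.88 and 7.19) and Oas3 (3.58 and 2.1) fell. A response of part of the list stays open, as does an effect of SPC on Gbp2 and Gbp5 alone. The Gbp5 call was lost without control library 2 (adjusted p = 0.116), without SPC library 2 (0.126) and without both (0.492), and the Gbp2 call without both (0.0934).

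The list calls could come from GC content or transcript length trends that differ between libraries. After each library was corrected for these trends, 9 of the 9 called lists still passed in the same direction, which argues against those trends as the whole cause. The histone call rested on control library 3, whose histone share was 0.0125%, against 0.00749% and 0.00764% in the other controls. The share was 0.00689% to 0.00778% with SPC, and the camera call was lost without control library 3 (adjusted p = 0.75). A change with SPC and genes that vary together within lists stay open for the others, as the calls did not hold with an estimated correlation.

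Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real grouping, the real one itself, with 59 genes against at most 0 in the others. In the blocked test, 1 of the 4 splits that part all 3 pairs gave as many, again the real one, with 866 genes against at most 0. The other 3 each exchange the group labels within 1 pair. The splits are too few for a share under 0.05.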
